A study of Mus musculus with 12 samples.

How the data were processed

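Total RNA from mouse kidney tubuloids was sequenced after 12 h of treatment. Per the labels, renal cortex of 4 wildtype mice was dissociated and the tubular epithelial cells were grown in Matrigel. The treatments were vehicle, myoglobin, and myoglobin with 100 nM dexamethasone, with 4 libraries each and 12 libraries in all. RNA was taken with a column kit that included a DNase step, and stranded messenger RNA libraries were made from it. The labels number the libraries of each treatment from 1 to 4 and do not say that a number stands for a mouse. The p-values therefore measure only the spread between these samples.

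The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.10a, Picard 2.27.4, featureCounts 2.0.3 and DESeq2 1.36.0 with the mouse genome build mm10, without the role of each. The deposited table holds whole numbers for 20819 genes, 15422 of them protein coding, and 0 genes of the mitochondrial chromosome. It is read here as a normalised score: the deposited values are reads per gene divided by a size factor of the library and then rounded, because each library skips or doubles whole numbers at the step its factor gives. The size factors read from these steps were 1.04 to 1.11 with vehicle, 0.989 to 1.11 with myoglobin, and 0.904, 0.971, 1.04 and 0.569 in replicates 1 to 4 with myoglobin and dexamethasone. The estimated reads in genes were 3.25 to 5.93 M per library. Coordinates are those of the table, and 20592 genes (98.9%) have the same ones in GENCODE M21, which also gave exonic lengths.

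In the vehicle group the spread between libraries, relative to the mean, was lower for genes with many reads per exonic base. The median ratio of variance to mean went from 1.05 below 0.03 reads per base to 0.641 above 0.3. With myoglobin it went from 1.13 to 0.688 at 0.1 to 0.2 reads per base and 1.16 above 0.3. With both agents, where replicate 4 stands apart, it went from 1.62 to 1.95 and 23.7. Among protein-coding genes with a mean of at least 30, the value rose with exonic length (Spearman rho 0.409 across genes, which are not independent replicates). Fold changes of densely covered transcripts may be too small, but these values do not settle it. With 4 libraries the median ratio of variance to mean lies below 1 for independent reads as well. The rise with exonic length does not show a limit either. The precision also depends on the 4 libraries per group and on the estimated reads per library.

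Tests of counts had been planned, and because the values are not counts, the planned replacement was used: limma-trend (limma 3.58.1 in R 4.3.3) on log2 of the value plus a pseudocount of 1, with the 3 groups as terms and 1 estimate of the spread shared by the 12 libraries. The deposited scaling was kept. Genes with a value of at least 10 in at least 4 libraries were tested, 14558 in number. P-values are two-sided and Benjamini-Hochberg adjusted over these genes within each of the 3 comparisons, and a gene passed at an adjusted p below 0.05. "Rose" and "fell" are used only of genes that passed. Changes are log2 fold changes ± SE, and group values are means ± SD of the deposited values with n = 4. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

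Before the data were examined, 20 lists with 651 genes were fixed, of which 608 genes are in the table. The 13 main lists are glucocorticoid targets, tubular injury, proximal tubule, NRF2 with haem and iron handling, integrated stress and unfolded protein response, NF-kB with inflammation, p53 targets, proliferation, fatty acid and mitochondrial metabolism, immediate early genes, hypoxia with glycolysis, cell death, and matrix with TGF-beta and YAP targets. The 7 check lists are markers of distal nephron, podocytes, fibroblasts and stroma, endothelium and immune cells, heat shock genes, and mitochondrially encoded genes. The last list has 0 members in the table and was not analysed, which left 19 lists. Each was tested against all other genes with camera (preset correlation 0.01), adjusted over the 19 lists of a comparison. Camera with an estimated correlation and fry, which asks whether the members of a list move one way on balance, were alternatives. Members that passed were also counted with the p-values "adjusted over the list alone".

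The rule for named genes was fixed at the same time. It takes Fkbp5, Tsc22d3, Per1, Hmox1, Havcr1, Lcn2 and Nr3c1 whatever their result. It adds the 5 largest rises and the 5 largest falls among passing genes whose groups do not overlap, leaving out predicted genes. It also adds the 2 passing members of each main list with the smallest p, or the 1 member with the smallest p where none passed, and the 1 such member of each check list. For myoglobin with dexamethasone against vehicle, only lists that camera called give names. Of the genes that passed in both contrasts of the overlap, the 5 in each direction class with the smallest larger p are named. Not every gene that the rule takes is printed. Further list members given as examples were chosen after their values were seen.

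The code was tested on simulated data with 100 changed genes per fold in each of 3 draws. The changed genes were drawn from those with a mean value of at least 30. All genes had the same dispersion, libraries were independent, and no library deviated with reads per exonic base. The shares below therefore check the code and do not give the power or the share of false calls in these data. Of genes changed 1.5-fold, 92.3% were recovered for myoglobin against vehicle, 95% for dexamethasone within myoglobin and 93.7% for both against vehicle. Of genes changed 2-fold the shares were 100%, 100% and 99.3%. Calls on unchanged genes made up 3.7%, 4.7% and 5.2%.

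The overlap of the myoglobin and the dexamethasone response shares the myoglobin libraries, so 100 data sets without group differences were simulated from the residuals. The first form changed the sign of each library's residuals at random. After its result was seen, a second form was added that draws random combinations of the residuals within each group, since sign changes give no spread where all signs of a group are alike; both are reported. The myoglobin libraries were also split 2 and 2 between the contrasts in all 6 ways.

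The alternatives fixed beforehand were median-ratio, upper-quartile and library-total scaling, no filter on low values or 1 per M in 4 libraries, pseudocounts of 0.1 and 10, a threshold of 0.01. They also took the replicate number as a block, fits to 2 groups only, leaving out each replicate, and list tests without genes of more than 1 list. Quantile normalization, library weights, a correction for the position limit, the list and overlap results without replicate 4 of myoglobin with dexamethasone, and leaving out a library of the group outside the comparison were chosen after seeing the data. A quantity was compared with all 35 splits of its 8 libraries into 4 and 4. Sequence reads were not used here.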

Results

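Mouse kidney tubuloids, clusters of tubular epithelial cells grown from renal cortex, were treated for 12 h with vehicle, with myoglobin, or with myoglobin and 100 nM dexamethasone. Myoglobin is the haem protein of muscle, named in the series' design as the injuring agent, and dexamethasone is a synthetic glucocorticoid. Messenger RNA of 4 libraries per treatment was measured as normalised read counts per gene. The deposited values of a library sum to 5.25 to 5.29 M with vehicle, 5.32 to 5.35 M with myoglobin, and 5.34 to 5.73 M with both. The estimated reads before scaling were 5.51 to 5.87 M, 5.28 to 5.93 M and 3.25 to 5.53 M. Replicate 4 of myoglobin with dexamethasone is the library with 3.25 M reads, and 2179 genes are listed at 0 in it against 1051 to 1544 in the other 11 libraries. Relative to the other 3 libraries of its group, its median gene deviated by -0.21 on the log2 scale below 0.03 reads per exonic base and by 0.40 above 0.3.

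**Figure D1:**
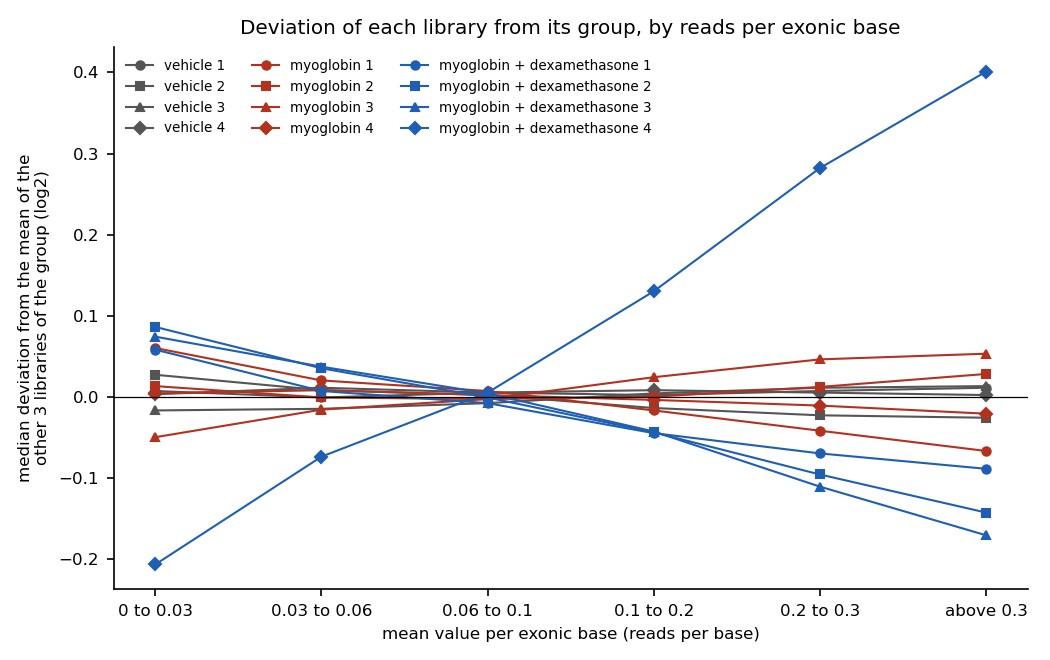
Median log2 deviation of each of the 12 libraries from the mean of the other 3 libraries of its group, for protein-coding genes binned by reads per exonic base. Replicate 4 of myoglobin with dexamethasone goes from -0.207 in the lowest bin to 0.401 in the highest.

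The first comparison asks what myoglobin changes in tubuloids without a glucocorticoid. Hmox1, the haem oxygenase that breaks down haem (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589, mm10), rose by 2.02 ± 0.062 on the log2 scale, from 113 ± 7.72 to 460 ± 13.7 (n = 4 libraries per group). Tnf, the cytokine, went from 181 ± 4.79 to 459.5 ± 7.94, Ccl20, a chemokine, rose by 1.99 ± 0.070, and Nos2, the inducible nitric oxide synthase, rose by 3.69 ± 0.28. The deepest fall among the named genes was that of Hsd11b2, a gene of the distal nephron, which inactivates corticosterone (ENSMUSG00000031891, chromosome 8, 105518755 to 105523988), from 182 ± 37.4 to 6.25 ± 2.22 (-4.68 ± 0.28). The 2 injury markers went apart. Lcn2, a secreted iron-trapping protein (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose by 0.44 ± 0.086. Havcr1, the kidney injury molecule (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), fell by 1.66 ± 0.35, from 48.8 ± 15.6 to 16.3 ± 8.06 (limma adjusted p 0.00361).

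**Figure D2:**
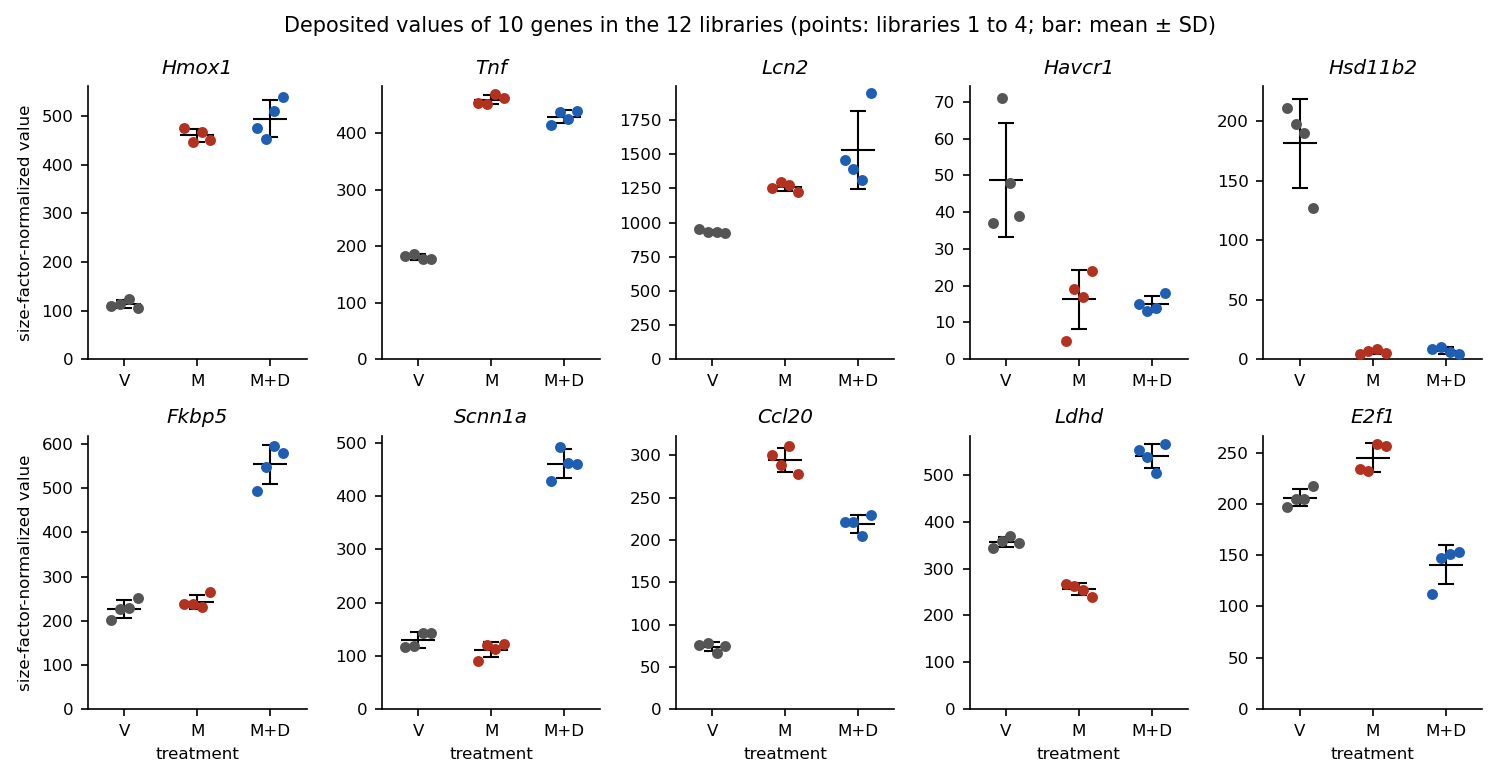
Deposited normalised read counts of 10 genes in each of the 4 libraries per treatment, on linear axes from 0, as points with the group mean and SD. Hmox1 is at 113 with vehicle and 460 with myoglobin, and Fkbp5 at 243 with myoglobin and 554 with myoglobin and dexamethasone.

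In the NF-kB and inflammation list, 32 of 42 tested members rose and 1 fell (33 and 1 adjusted over the list alone), with camera at an adjusted p of 1.47e-32 and 1.21e-04 with an estimated correlation. Among them, Cfb, a factor of the alternative complement pathway, rose by 2.31 ± 0.13, Csf2, a myeloid growth factor, by 1.95 ± 0.21, and the neutrophil chemokine gene Cxcl2 by 1.71 ± 0.096. Traf1, an adaptor of TNF receptors, was the member that fell (-0.72 ± 0.14). In the NRF2, haem and iron list, 21 of 39 tested members rose and 1 fell (23 and 1 adjusted over the list alone), with camera at an adjusted p of 4.04e-13 (adjusted p = 0.262 with an estimated correlation). Slc11a2, an iron transporter, rose by 0.61 ± 0.033, Nqo1, a quinone reductase, by 0.90 ± 0.13, and Slc7a11, the cystine importer, by 1.34 ± 0.10. In the integrated stress and unfolded protein list, 25 of 43 tested members rose and 2 fell (30 and 2 adjusted over the list alone), with camera at 9.77e-12 (adjusted p = 0.262 with an estimated correlation). Stc2, a secreted glycoprotein, rose by 0.72 ± 0.051 and the transcription factor Atf5 by 0.68 ± 0.058. Chac1, which degrades glutathione, rose by 1.81 ± 0.16, and Asns, the asparagine synthetase, by 0.75 ± 0.092. Atf3, a stress-induced transcription factor, fell (-0.79 ± 0.12).

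In the distal nephron list, 3 of 23 tested members rose and 13 fell (4 and 15 adjusted over the list alone), with camera at an adjusted p of 3.41e-07 (adjusted p = 0.0871 with an estimated correlation). Besides Hsd11b2, the vasopressin-regulated water channel gene Aqp2 fell (-2.58 ± 0.38), as did Foxi1, a transcription factor of intercalated cells (-2.51 ± 0.26). The members that rose were Slc26a4, an anion exchanger of intercalated cells, by 1.05 ± 0.19, Calb1, a calcium-binding protein of the distal tubule, by 0.31 ± 0.079, and Wnk1, a kinase that regulates salt transport, by 0.11 ± 0.036. In the immediate early list, 3 of 37 tested members rose and 7 fell (3 and 10 adjusted over the list alone), with camera at 0.0231 (adjusted p = 0.728 with an estimated correlation). Egr1 fell (-0.99 ± 0.096) and Jun fell (-0.42 ± 0.043), while Fos, the partner of Jun, rose by 0.52 ± 0.14. In the cell death list, 9 of 43 tested members rose and 3 fell (11 and 3 adjusted over the list alone), with camera at 0.0263 (adjusted p = 0.203 with an estimated correlation). The members that rose act in different ways: Slc7a11 protects cells from lipid peroxidation, Chac1 lowers glutathione, Fas is a death receptor (1.41 ± 0.13), and Casp1 and Casp4 are inflammatory caspases (0.98 ± 0.15 and 0.70 ± 0.076). Gsdmc2, a gasdermin, fell (-2.15 ± 0.36). Without genes of more than 1 list, the immediate early and cell death lists lost the call (adjusted p 0.0996 and 0.326), and fry did not call the immediate early list (0.0633).

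Camera called no other list for myoglobin. Of the glucocorticoid targets, 8 rose and 8 fell of 37, or 9 and 11 adjusted over the list alone (adjusted p 0.747). Cebpd, a transcription factor, rose by 1.26 ± 0.072 and Tnfaip3, an inhibitor of NF-kB signalling, by 0.90 ± 0.057. Tsc22d3, a glucocorticoid-induced gene, rose by 0.36 ± 0.072, and Fkbp5, Per1 and the receptor gene Nr3c1 stood at 0.10 ± 0.073, -0.01 ± 0.065 and 0.01 ± 0.054 without passing (limma adjusted p 0.418, 0.912 and 0.959). In the injury list the counts were 5 rose and 4 fell of 39, or 5 and 4 adjusted over the list alone (0.747), with rises of Cxcl16, a chemokine (0.91 ± 0.053), and Vcam1, an adhesion molecule (0.82 ± 0.050). Proximal tubule genes counted 3 rose and 4 fell of 21, or 3 and 7 adjusted over the list alone (0.317). Napsa, an aspartic protease, fell (-0.63 ± 0.060) and Slc5a1, a sodium-glucose transporter, rose (0.46 ± 0.059). For p53 targets 5 rose and 3 fell of 35, or 6 and 5 adjusted over the list alone (0.747), with Fas up and Ddit4l down (-0.39 ± 0.052). For fatty acid metabolism 4 rose and 2 fell of 35, or 4 and 2 adjusted over the list alone (0.747). Cpt1a, which brings fatty acids into mitochondria, fell (-0.51 ± 0.037) and Vnn1, a pantetheinase, rose (1.41 ± 0.11). For hypoxia and glycolysis 8 rose and 3 fell of 42, or 8 and 3 adjusted over the list alone (0.0947, 0.0498 without replicate 4 of myoglobin with dexamethasone, 0.0016 without all libraries numbered 3, and 0.0214 without the low-value filter), with Ndrg1 down (-0.45 ± 0.058) and the collagen hydroxylase gene P4ha2 up (0.63 ± 0.089). For matrix genes 9 rose and 8 fell of 44, or 9 and 9 adjusted over the list alone (0.317), with Tgfbi down (-1.67 ± 0.13) and the integrin gene Itga2 up (0.61 ± 0.051).

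In the proliferation list limma called 0 of 47 members, also adjusted over the list alone, against 3 at an unadjusted p below 0.05, and camera and fry gave adjusted p-values of 0.747 and 0.912. E2f1, a regulator of S phase entry, stood at 0.25 ± 0.089 (limma adjusted p 0.067, and 0.0405 without replicate 4 of myoglobin with dexamethasone). Markers of other cell types moved as follows. Of 9 podocyte markers limma called 0 against 2 unadjusted (camera 0.317, fry 0.37), and Podxl stood at -0.33 ± 0.13. Of 6 endothelial markers it called 0 against 1 unadjusted (camera 0.317, fry 0.057), and Flt1 stood at -0.57 ± 0.22. Of fibroblast markers 0 rose and 2 fell of 12, or 0 and 2 adjusted over the list alone (camera 0.257), with Rgs5, a pericyte gene, down (-0.63 ± 0.12). Of immune markers 1 rose and 1 fell of 6, or 1 and 1 adjusted over the list alone (camera 0.747). Cd74, the invariant chain, rose (1.03 ± 0.068) and Ptprc, the leukocyte antigen CD45, fell (-0.38 ± 0.063). Of heat shock genes 2 rose and 1 fell of 18, or 2 and 1 adjusted over the list alone (camera 0.281), with Hsph1 up (0.22 ± 0.051; limma adjusted p 0.00647, and 0.0526 and 0.0911 without all libraries numbered 2 or 3). Median and mean differed in sign for the proliferation, p53 and fatty acid lists. Without replicate 4 of myoglobin with dexamethasone, several counts for myoglobin moved by over 1.5 times. In the injury list 8 rose and 8 fell, in the immediate early list 11 fell, and in the p53 list 5 fell. In the fatty acid list 4 fell, in the proliferation list 2 rose, and in the heat shock list 5 rose.

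In all, limma called 2669 of 14558 genes (18.3%) for myoglobin against vehicle, 1268 higher and 1401 lower, and 403 of them changed at least 2-fold (195 higher, 208 lower). At an unadjusted p below 0.05 there were 4392. In 3644 genes (25.03%) the 4 libraries of one group all lay above those of the other, where chance gives 2.86%. The largest rises beside Nos2 were those of Lbhd2 (3.75 ± 0.31), Fyb, an adaptor of blood cell signalling (3.72 ± 0.20), Gpr84, a fatty acid receptor (3.71 ± 0.29), and Serpina3f, a protease inhibitor (3.63 ± 0.24). The largest falls beside Hsd11b2, Aqp2 and Foxi1 were those of Adh6a, an alcohol dehydrogenase (-3.07 ± 0.26), and Rhcg, an ammonia channel (-2.79 ± 0.28). These folds and their order depend on the pseudocount, since the lower group of each has a mean below 10. With pseudocounts of 10 and 0.1, Lbhd2 went from 2.16 to 4.21, Gpr84 from 1.81 to 4.41 and Nos2 from 2.53 to 3.92. The balance of calls depends on the scaling and on 1 library: it was 1055 higher and 1663 lower with upper-quartile scaling, and 1926 higher and 1868 lower without replicate 4 of myoglobin with dexamethasone. Below 0.03 reads per exonic base the median change was -0.13, with 258 genes called higher and 557 lower, and with quantile normalization it was -0.03, with 356 higher and 435 lower.

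**Figure D3:**
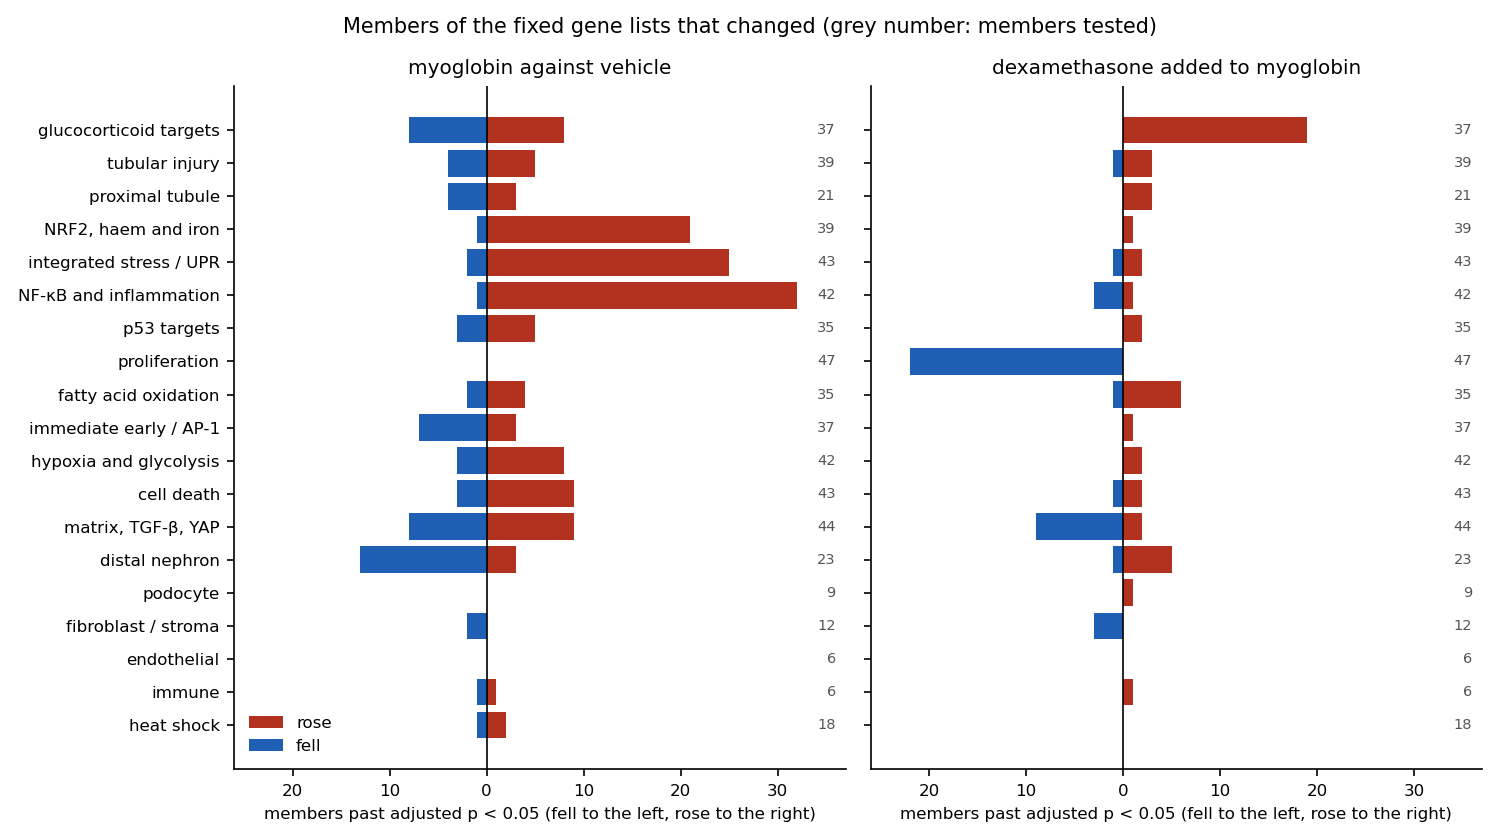
Members of each fixed gene list that rose (to the right) or fell (to the left) past an adjusted p of 0.05, for myoglobin against vehicle and for dexamethasone within myoglobin. With myoglobin 32 members of the NF-kB list rose, and with dexamethasone 22 members of the proliferation list fell.

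The second comparison asks what dexamethasone changes in tubuloids that also receive myoglobin. Fkbp5, a chaperone partner of the receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527, mm10), rose by 1.19 ± 0.073, from 243 ± 15.4 to 554 ± 45.0 (n = 4 libraries per group). The clock gene Per1 rose by 0.71 ± 0.065 and Tsc22d3 by 0.45 ± 0.072. Scnn1a, a subunit of the epithelial sodium channel (ENSMUSG00000030340, chromosome 6, 125320659 to 125344943), rose by 2.05 ± 0.097, from 112 ± 14.4 to 461 ± 26.6. E2f1, of the cell cycle (ENSMUSG00000027490, chromosome 2, 154559407 to 154569892), fell from 245 ± 13.9 to 141 ± 19.3 (-0.80 ± 0.089), and Ccne2, a cyclin of S phase entry, fell as well (-0.71 ± 0.093). Hmox1 and Havcr1 stood at 0.10 ± 0.062 and 0.06 ± 0.35 without passing (limma adjusted p 0.352 and 0.942). Lcn2 stood at 0.26 ± 0.086 (limma adjusted p 0.0848, and 0.0224 without replicate 4 of myoglobin with dexamethasone), and the receptor gene Nr3c1 fell (-0.25 ± 0.054; adjusted p 0.0108, and 0.0549 and 0.0653 without all libraries numbered 1 or 2).

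Of the glucocorticoid targets, 19 of 37 tested members rose and 0 fell (23 and 1 adjusted over the list alone), with camera at an adjusted p of 2.36e-18 and 1.56e-04 with an estimated correlation. Zbtb16, a zinc finger gene (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222), went from 0.5 ± 0.577 to 32 ± 8.12; its change of 4.51 ± 0.40 depends on the pseudocount, since the lower group lies near 0. Sgk1, a kinase that raises sodium uptake, rose by 1.88 ± 0.19. In the proliferation list, 0 of 47 tested members rose and 22 fell (0 and 33 adjusted over the list alone), with camera at 5.55e-20 (adjusted p = 0.451 with an estimated correlation). Cdt1 and Cdc6, which load the replicative helicase, fell (-0.62 ± 0.14 and -0.60 ± 0.097). In fatty acid and mitochondrial metabolism, 6 of 35 tested members rose and 1 fell (9 and 2 adjusted over the list alone), with camera at 7.17e-04 (adjusted p = 0.221 with an estimated correlation). Acadm, a dehydrogenase of fatty acid oxidation, rose by 0.26 ± 0.052 and Crat, a carnitine acetyltransferase, by 0.29 ± 0.059, while Vnn1 fell (-0.53 ± 0.11). In the matrix list, 2 of 44 tested members rose and 9 fell (3 and 13 adjusted over the list alone), with camera at 0.023 (adjusted p = 0.737 with an estimated correlation). Ccn1, a YAP target, fell (-0.76 ± 0.10), as did Timp3, an inhibitor of matrix proteases (-0.73 ± 0.096).

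In the distal nephron list, 5 of 23 tested members rose and 1 fell (5 and 1 adjusted over the list alone), with camera at an adjusted p of 0.0366 (adjusted p = 0.486 with an estimated correlation). Beside Scnn1a, Foxi1 rose by 0.97 ± 0.26 and Calb1 by 0.30 ± 0.079, and Cldn19, a tight junction gene of the thick limb, fell (-0.48 ± 0.12). In the fibroblast list, 0 of 12 tested members rose and 3 fell (0 and 4 adjusted over the list alone), with camera at 0.00519 (adjusted p = 0.221 with an estimated correlation). Col6a3, a collagen chain, fell from 11.5 ± 1.73 to 3.75 ± 3.20, and Acta2, smooth muscle actin, fell (-0.55 ± 0.15). In replicate 4 of myoglobin with dexamethasone the median deviation of the fibroblast markers was -0.40, and without that library 1 of the 12 fell in place of 3 (camera 0.0176). In the NRF2 list, 1 of 39 tested members rose and 0 fell (1 and 0 adjusted over the list alone), with camera at 0.013 (adjusted p = 0.737 with an estimated correlation). Without that replicate camera gave 0.269. Its member that rose was Gclc, of glutathione synthesis (0.26 ± 0.057). Fry did not call the NRF2 and matrix lists (adjusted p 0.408 and 0.322). The matrix list also lost the call without genes of more than 1 list (0.0919), with library totals (0.0529) and without all libraries numbered 3 (0.0539). The NRF2 list lost it with quantile normalization (0.0649) and without all libraries numbered 4 (0.495), and the distal nephron list without all libraries numbered 1 or 3 (0.0654 and 0.0539).

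Camera called no other list for dexamethasone. In the NF-kB list 1 rose and 3 fell of 42, or 1 and 4 adjusted over the list alone (adjusted p 0.0885, 0.0328 without replicate 4 of myoglobin with dexamethasone, and 0.0293 with the replicate number as a block). Csf2 fell (-0.94 ± 0.21), the chemokine gene Cxcl10 fell (-0.78 ± 0.15), Ccl20 fell (-0.43 ± 0.070) and the cytokine gene Il34 rose (0.39 ± 0.060). In the injury list 3 rose and 1 fell of 39, or 3 and 1 adjusted over the list alone (0.173), with Fga, a fibrinogen chain, up (1.21 ± 0.23). Proximal tubule genes counted 3 rose and 0 fell of 21, or 3 and 0 adjusted over the list alone (0.0961). Napsa rose (0.45 ± 0.060). Integrated stress genes counted 2 rose and 1 fell of 43, or 3 and 1 adjusted over the list alone (0.0961), with Stc2 down (-0.38 ± 0.051) and Sesn2, a stress-induced inhibitor of mTORC1, up (0.19 ± 0.044). For p53 targets 2 rose and 0 fell of 35, or 2 and 0 adjusted over the list alone (0.601), Sesn2 and Trp53inp1 (0.20 ± 0.049). For immediate early genes 1 rose and 0 fell of 37, or 1 and 0 adjusted over the list alone (0.795), with Zfp36, which destabilises messenger RNA, up (0.27 ± 0.053). For hypoxia and glycolysis 2 rose and 0 fell of 42, or 3 and 1 adjusted over the list alone (0.0961), with the glucose transporter gene Slc2a3 (1.40 ± 0.27) and Aldoc (0.28 ± 0.064) up. For cell death 2 rose and 1 fell of 43, or 2 and 1 adjusted over the list alone (0.889). Pycard, the inflammasome adaptor, rose (0.28 ± 0.049), Acsl4, which feeds lipid peroxidation, rose (0.25 ± 0.056) and Bcl2l11, a pro-apoptotic gene, fell (-0.31 ± 0.084). For podocyte markers 1 rose and 0 fell of 9, or 1 and 3 adjusted over the list alone (0.124), with Synpo up (0.29 ± 0.079), and for immune markers 1 rose and 0 fell of 6, or 1 and 0 adjusted over the list alone (0.448), with Ptprc up (0.31 ± 0.063). Limma called 0 of 6 endothelial markers against 1 unadjusted (camera 0.889, fry 0.81; Ehd3 0.23 ± 0.10) and 0 of 18 heat shock genes against 2 unadjusted (camera 0.0961, fry 0.472; Hspa1b 0.23 ± 0.091). Without replicate 4 of myoglobin with dexamethasone, 4 members of the injury list rose and 3 fell, 2 and 2 of the immediate early list, 4 and 3 of the cell death list, 3 and 1 of the p53 list, 1 and 1 of the NRF2 list and 1 and 1 of the immune list. The direction of camera then turned down for the injury and p53 lists and up for the endothelial list, none of which it called. Other settings called further lists. Without genes of more than 1 list these were the injury list, up, and the NF-kB list, down (0.0162 and 0.0466), and with fry the proximal tubule list, up (0.0316). Without the low-value filter they were the stress list, up, and the NF-kB list, down (both 0.0392). Without all libraries numbered 2 or 3, the injury, stress, hypoxia and heat shock lists were called up (0.0168 to 0.0481). So was the proximal tubule list without number 2 (0.0481), while the podocyte list was called down without number 1 (0.01) and the NF-kB list without number 4 (0.0166) and with quantile normalization (0.0277).

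In all, limma called 1016 of 14558 genes (6.98%) for dexamethasone within myoglobin, 448 higher and 568 lower, with 58 changed at least 2-fold (35 higher, 23 lower) and 3226 at an unadjusted p below 0.05. In 1924 genes (13.2%) the groups did not overlap, where chance gives 2.86%. The largest rises after Zbtb16 were those of Cwh43, which remodels lipid anchors (2.88 ± 0.22), Wfdc6a (2.77 ± 0.47), Abcb5, a membrane transporter (2.67 ± 0.27), and Sult1d1, a sulfotransferase (65.8 ± 1.5 to 322 ± 7.04). The largest falls were those of Pappa, a protease of growth factor binding proteins (-1.90 ± 0.34), Col6a3 (-1.68 ± 0.45), the matrix protease gene Mmp3 (-1.52 ± 0.39), Dpysl4 (-1.49 ± 0.37) and Cfap43, of cilia and flagella (-1.44 ± 0.29). The folds of Wfdc6a, Pappa, Col6a3, Dpysl4 and Cfap43 depend on the pseudocount, since their lower group has a mean below 5: that of Wfdc6a was 1.06 with a pseudocount of 10 and 4.00 with 0.1. Scaling by library totals gave 384 higher and 717 lower. The count was 617 without replicate 2 of myoglobin and 551 without its replicate 4. Leaving out single libraries ended the call of 7 named genes. Without 1 of the myoglobin libraries, these were Col6a3 and Synpo (replicates 1 to 4, and 1, 3 and 4), Dpysl4, Trp53inp1 and Sesn2 (replicates 2 to 4), Mmp3 (3 and 4) and Aldoc (3). Without 1 library given both agents, they were Col6a3 and Dpysl4 (replicates 2 and 3), Synpo (1 to 3), Trp53inp1 (1 and 3), Mmp3 (2 and 4) and Sesn2 (3). The adjusted p then reached 0.0924 for Col6a3, 0.0989 for Synpo, 0.0826 for Dpysl4, 0.0821 for Trp53inp1, 0.0704 for Sesn2, 0.0927 for Mmp3 and 0.0522 for Aldoc. In other settings, Trp53inp1 and Synpo lost the call with library totals (0.0846 and 0.0653), as did Trp53inp1 with quantile normalization (0.0791) and Dpysl4 with a pseudocount of 10 (0.0666). In a fit to 2 groups only, Col6a3, Trp53inp1 and Synpo lost it (0.0733, 0.055 and 0.0511). Without all libraries of 1 number, 21 of the 54 named calls ended: beside these 7 genes and Nr3c1, they were Cfap43, Gclc, Acadm, Crat, Zfp36, Acsl4, Ptprc, Thbs1, Fndc1, Fga, Pycard, Aldh3a2 and Arrdc2. Of 1079 genes above 0.2 reads per exonic base, 61 were called higher and 2 lower, and 84 and 15 without replicate 4 of myoglobin with dexamethasone.

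The third comparison, myoglobin with dexamethasone against vehicle, shows the joint effect of both agents. Hmox1 rose by 2.12 ± 0.062, Tnf by 1.24 ± 0.042 and Csf1, a macrophage growth factor, by 1.12 ± 0.045 (n = 4 libraries per group). Fkbp5 rose by 1.28 ± 0.073, Tsc22d3 by 0.81 ± 0.072 and Per1 by 0.70 ± 0.065, and Nr3c1 fell (-0.24 ± 0.054). Lcn2 rose by 0.70 ± 0.086, from 933 ± 12.4 to 1529 ± 285, and Havcr1 fell from 48.8 ± 15.6 to 15 ± 2.16 (limma adjusted p 0.00353, and 0.0519 without all libraries numbered 2). The Lcn2 value of 1947 in replicate 4 of myoglobin with dexamethasone lay above those of replicates 1 to 3 (1460, 1395 and 1314). Over the other settings the change of Lcn2 was 0.569 to 0.838. Hsd11b2 was at 7.25 ± 2.75, against 182 ± 37.4 with vehicle (-4.51 ± 0.28).

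Camera called 14 of 19 lists, 8 up and 6 down, and 2 of them also with an estimated correlation. Those 2 were the NF-kB list, where 31 of 42 tested members rose and 1 fell (31 and 1 adjusted over the list alone; adjusted p 2.07e-21, and 6.76e-04 with an estimated correlation), and the glucocorticoid targets, where 20 of 37 tested members rose and 3 fell (22 and 5 adjusted over the list alone; 3.50e-08, and 0.00255 with an estimated correlation). Cebpd, a member of the glucocorticoid list, rose by 1.29 ± 0.072. Its mean was 147 with vehicle, 352 with myoglobin alone and 361 with both agents, so most of this rise was there without dexamethasone. In the NRF2 list 31 of 39 tested members rose and 1 fell (33 and 1 adjusted over the list alone; camera 1.22e-14, adjusted p = 0.173 with an estimated correlation), with Slc11a2 up (0.56 ± 0.033). In the stress and unfolded protein list 33 of 43 tested members rose and 1 fell (37 and 1 adjusted over the list alone; camera 2.56e-13, adjusted p = 0.173 with an estimated correlation), with Atf5 (0.75 ± 0.058) and Herpud1, of protein degradation at the endoplasmic reticulum (0.87 ± 0.073), up. In hypoxia and glycolysis 13 of 42 tested members rose and 3 fell (14 and 3 adjusted over the list alone; camera 0.00559, adjusted p = 0.447 with an estimated correlation), with the oxygen sensor gene Egln3 (0.51 ± 0.066) and hexokinase gene Hk2 (0.51 ± 0.067) up. In fatty acid metabolism 8 of 35 tested members rose and 1 fell (8 and 1 adjusted over the list alone; camera 0.022, adjusted p = 0.347 with an estimated correlation), with Vnn1 up (0.88 ± 0.11) and Cpt1a down (-0.36 ± 0.037). In the cell death list 14 of 43 tested members rose and 3 fell (15 and 4 adjusted over the list alone; camera 0.022, adjusted p = 0.173 with an estimated correlation), with Slc7a11 (1.11 ± 0.10) and Casp4 (0.73 ± 0.076) up. Of heat shock genes 4 of 18 tested members rose and 1 fell (7 and 1 adjusted over the list alone; camera 0.0216, or 0.0513 without replicate 4 of myoglobin with dexamethasone; adjusted p = 0.493 with an estimated correlation), with Bag3 up (0.25 ± 0.057).

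The lists called down were the following. In the proliferation list 0 of 47 tested members rose and 29 fell (0 and 38 adjusted over the list alone; camera 1.03e-10, adjusted p = 0.447 with an estimated correlation), with Ccne2 (-0.61 ± 0.093) and E2f1 (-0.56 ± 0.089) down. In the fibroblast list 0 of 12 tested members rose and 6 fell (0 and 6 adjusted over the list alone; camera 0.00236, adjusted p = 0.173 with an estimated correlation), with Rgs5 down (-1.08 ± 0.12). In the distal nephron list 5 of 23 tested members rose and 13 fell (7 and 13 adjusted over the list alone; camera 0.00834, adjusted p = 0.291 with an estimated correlation), with Scnn1a up (1.82 ± 0.097). In the matrix list 9 of 44 tested members rose and 16 fell (9 and 17 adjusted over the list alone; camera 0.022, adjusted p = 0.493 with an estimated correlation), with Tgfbi (-1.97 ± 0.13) and Timp3 (-1.33 ± 0.096) down. In the immediate early list 4 of 37 tested members rose and 9 fell (4 and 9 adjusted over the list alone; camera 0.0319, adjusted p = 0.493 with an estimated correlation), with Jun (-0.53 ± 0.043) and Egr1 (-1.17 ± 0.096) down. Of podocyte markers 1 of 9 tested members rose and 2 fell (1 and 6 adjusted over the list alone; camera 0.042, or 0.0762 without replicate 4 of myoglobin with dexamethasone; adjusted p = 0.472 with an estimated correlation). Camera did not call the injury list (6 rose and 6 fell of 39, or 7 and 6 adjusted over the list alone; 0.391), the proximal tubule list (3 rose and 2 fell of 21, or 3 and 2; 0.837), p53 targets (6 rose and 5 fell of 35, or 7 and 5; 0.437), endothelial markers (0 rose and 1 fell of 6, or 0 and 0; 0.342) or immune markers (1 rose and 2 fell of 6, or 1 and 2; 0.79). Fry did not call the podocyte and heat shock lists (adjusted p 0.0542 and 0.0633), but called the endothelial list, down (0.0385). Without genes of more than 1 list, the cell death, matrix and podocyte lists lost the call (0.167, 0.0795 and 0.0795). The podocyte list also lost it with library totals (0.0927) and quantile normalization (0.14). Without all libraries of 1 number, these lost the call: hypoxia (number 1, 0.0771), immediate early genes (2 and 3, 0.0576 and 0.0981), matrix genes (3, 0.0786), and fatty acid metabolism and podocyte markers (4, 0.0723 and 0.193). For the proximal tubule list, median and mean were below 0 and the test's direction was up. Without replicate 4 of myoglobin with dexamethasone, 10 members of the injury list fell and camera's direction turned down without a call, 14 of the immediate early list and 5 of the cell death list fell, and limma called 0 endothelial markers, against 3 at an unadjusted p below 0.05 with all libraries.

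In all, limma called 4161 of 14558 genes (28.6%) for both agents against vehicle, 2029 higher and 2132 lower, with 493 changed at least 2-fold (187 higher, 306 lower) and 5909 at an unadjusted p below 0.05. In 4166 genes (28.6%) the groups did not overlap, where chance gives 2.86%. The largest rises were those of Zbtb16, Fyb (4.08 ± 0.20), Cyp1a1, a target of the aryl hydrocarbon receptor (3.70 ± 0.21), Serpina3f (3.68 ± 0.24) and Gpr84 (3.52 ± 0.29). The largest falls after Hsd11b2 were those of the gasdermin genes Gsdmc2 (-3.33 ± 0.36) and Gsdmc3 (-3.15 ± 0.31), Dio3, a deiodinase of thyroid hormone (-3.21 ± 0.41), and Tcp11 (-3.12 ± 0.48). The folds of genes near 0 depend on the pseudocount: with 0.1 and 10, Dio3 was at -4.36 and -1.40 and Tcp11 at -4.15 and -1.54, and Gpr84 at 4.21 and 1.67. Scaling by library totals gave 1565 higher and 2648 lower. The direction of calls also went with reads per exonic base. Below 0.03 reads per base 272 genes were called higher and 939 lower (median change -0.186). Above 0.2 these were 374 and 27 (median change 0.156). Without replicate 4 of myoglobin with dexamethasone they were 310 and 808 below 0.03, and 372 and 74 above 0.2. Without replicate 1, 2, 3 or 4 of the libraries with both agents, the balance turned to 1951 and 1930, 1962 and 1956, 2052 and 1940, and 2137 and 2088.

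The overlap of the first 2 comparisons asks whether dexamethasone moves genes changed by myoglobin back or further away. No library was given dexamethasone alone. An effect of dexamethasone that does not depend on myoglobin therefore cannot be told apart from a reversal of the myoglobin response. Of the genes tested, 166 fell with myoglobin and rose with dexamethasone. Ldhd, a lactate dehydrogenase, went from 357 ± 11.2 with vehicle to 256 ± 12.7 and 540.3 ± 26.6, and Pygl, the liver glycogen phosphorylase, from 316 ± 20.7 to 149.5 ± 11.6 and 238 ± 28.4. The others named here are AU015791 (-1.25 then 1.42 on the log2 scale), Tns1 (-0.49 then 0.39) and Acss1 (-0.53 then 0.71). Another 94 rose and then fell. They include Ccl20 (1.99 then -0.43), Stc2 (0.72 then -0.38), Hs6st2 (0.49 then -0.36), Pdzrn3 (1.41 then -0.40) and Gbp4 (1.12 then -0.62). A further 46 rose in both contrasts. They include Lpo, a peroxidase (means ± SD of 80.3 ± 2.5, 229.8 ± 11.3 and 395 ± 32.1 in the 3 groups), Serpina3n (0.89 then 1.67), Cldn1, a tight junction gene (0.50 then 0.35), Aldh3a2 (0.25 then 0.23) and Arrdc2 (0.57 then 0.45). In both contrasts 48 fell. They include Ccdc80 (-0.67 then -0.71), L1cam (-0.39 then -0.43), Timp3 (-0.60 then -0.73), Thbs1 (-0.38 then -0.35) and Fndc1 (-0.91 then -0.69).

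Independent lists would give 43.1 genes that fell and rose, 49.5 that rose and fell, 39 that rose in both and 54.7 that fell in both. The myoglobin libraries enter both contrasts with opposite sign. Data simulated without effects by random combinations of residuals gave 0 to 1213 genes in opposite directions (mean 15.2) and 0 to 39 in the same direction (mean 0.6), against 260 and 94 observed. Of the 100 sets, 1 had as many in opposite directions. Data simulated by sign changes gave 0 of either in all 100 sets. The covariance of the log2 changes was -0.0173, against means of -0.0109 with random combinations (-0.0651 to 0.00293) and -0.0110 with sign changes (-0.0311 to 0.00176). It was as low in 22 and 14 of the 100 sets. Pearson's r across genes was -0.186, with means of -0.436 and -0.471 in the 2 simulations; genes are not independent replicates. With the myoglobin libraries split 2 and 2 between the contrasts, 66 to 109 genes were opposite (mean 82.8) and 23 to 44 the same (mean 31.7), with a mean covariance of -0.00647 (-0.00898 to -0.00343). On average over these splits, 65.5 genes fell and then rose, where independent lists would give 12, and 17.3 rose and then fell (11.3). In both contrasts 16.2 rose (10.7) and 15.5 fell (12.8). The lower counts thus come with lower expectations, and the excess of genes that fell and then rose stayed without a shared library. Part of the excess over independent lists may come from the shared libraries, and none of these values is a test of a shared effect. Without replicate 4 of myoglobin with dexamethasone, 397 genes were opposite and 139 the same. With the replicate number as a block, 493 were opposite and 210 the same. The simulated data did not keep a pairing by number.

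**Figure D4:**
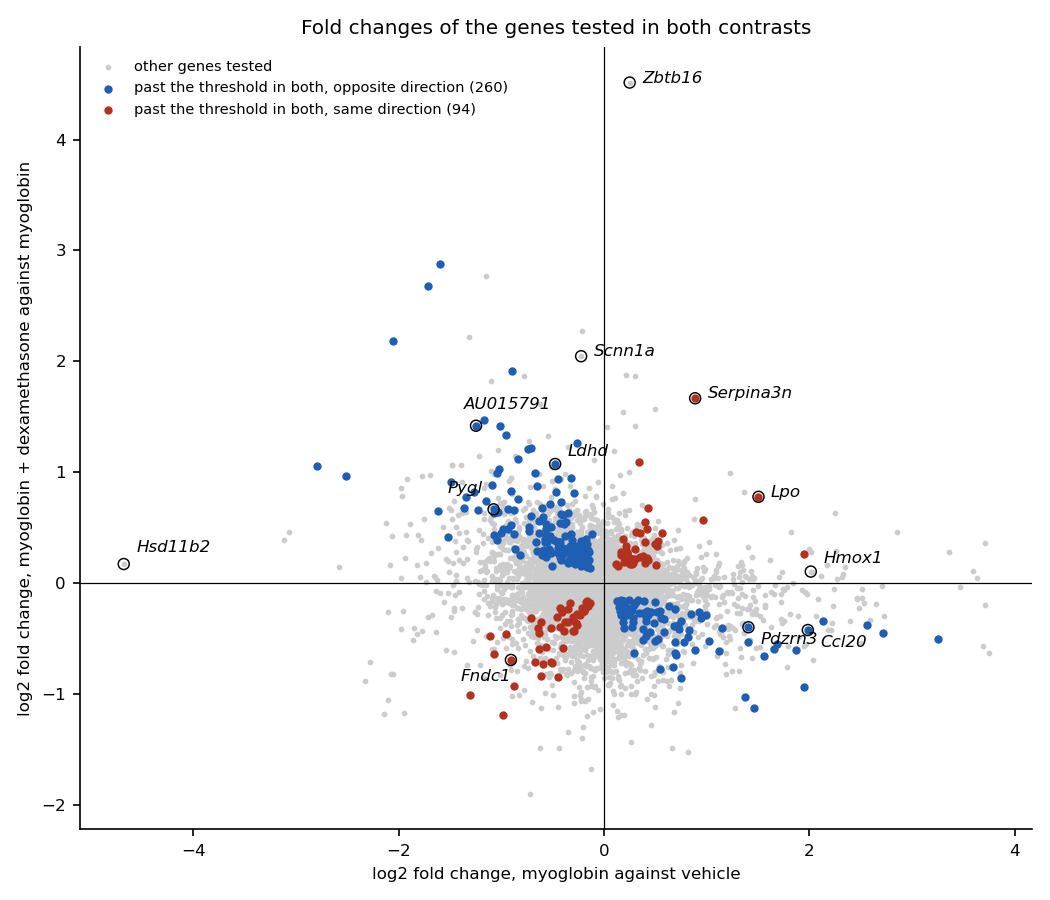
Log2 fold change of dexamethasone within myoglobin against that of myoglobin over vehicle, with 1 point per gene tested and black rings on the genes with labels. Of the genes that passed in both, 260 went in opposite directions (blue) and 94 in the same (red).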

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

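No test in this part was chosen after its result was seen. Within each group of 4 libraries, the values of 106 named genes and 4 quantities per library (total of the deposited values, size factor, genes listed at 0 and estimated reads) were searched for a highest or lowest library far from the other 3 relative to the group's range. Of 330 such searches 23 were positive, where chance alone gives about 1 in 20, or 16.5. Of the 23, 13 lie in the group with both agents, with 5 each in its replicates 1 and 4.

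With vehicle, Lcn2 was at 951 in replicate 1 (the others 924 to 928). Gpr84 was at 3 in vehicle replicate 3, with the others at 1. Jun was at 527 in vehicle replicate 4 (567 to 573 in the others). Zbtb16 was at 1 in vehicle replicate 1 and at 0 in the others. With myoglobin, replicate 3 had 8 for Foxi1 (6 in the others), 338 for Cebpd (356 to 359), 199 for Ccne2 (176 to 177) and 35 for Gsdmc2 (26 to 27). Egln3 was at 631 in myoglobin replicate 4 (692 to 696). Bag3 was at 413 in myoglobin replicate 1 (469 to 476).

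With myoglobin and dexamethasone, replicate 1 had 112 for E2f1 (147 to 153 in the others), 6 for Pappa (2), 6 for Dpysl4 (2), 300 for Il34 (290 to 291) and 91 for Ccne2 (116 to 120). Replicate 3 had 555 for Slc5a1 (551), 44 for Zbtb16 (26 to 29) and 121 for Ehd3 (104 to 106). Replicate 4 had 770 for Atf5 (636 to 645), 2056 for Acsl4 (1715 to 1738), 0 for Dio3 (2) and 1205 for Aldh3a2 (1086 to 1100). Its deposited values sum to 5.7252 M, against 5.3383 to 5.372 M in the other 3.

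Replicate 4 of myoglobin with dexamethasone stood apart in more than its total, with 3.25 M estimated reads and 2179 genes at 0. If fewer reads met a limit in the read positions that a transcript offers, its deviation should rise with reads per exonic base among genes of similar value: over 5361 genes with a mean of 200 to 600, Spearman's rho was 0.592, and -0.442 to 0.31 in the other 11 libraries. Such a limit is a candidate cause of the trend. The rho repeats, among genes of similar value, the trend with reads per exonic base already given for this library in the Results. A high rho could be foreseen from that trend, and it is no independent evidence for the limit. Among genes of similar value, reads per base depend mainly on exonic length. Any other trend with length would give the same, and this test cannot tell them apart. The other libraries with both agents were compared with means that include replicate 4. Replicate 3 of myoglobin reached 0.31 with 5.28 M estimated reads, the fewest of its group. Replicate 2 of that group, with 5.31 M, stood at -0.002, and replicate 1, with the most (5.93 M), at -0.22. With vehicle the order differed: replicate 4 had the fewest (5.51 M) and stood at 0.022, and replicate 3, with 5.63 M, at 0.209. A different share of another cell type stays open: the largest median deviation over the marker lists was -0.404 (fibroblast, quartiles -0.605 to 0.302), between the 0.3 and 0.5 set as bounds. No other biological explanation was tested, and the design names none that sets this library apart.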

How the results depend on the processing

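Quantile normalization, library weights, the position-limit correction, the lists and the overlap without replicate 4 of myoglobin with dexamethasone or under quantile normalization, the overlap under library totals, and counts without a library of the group outside the comparison were chosen after seeing the data. No named gene that passed turned direction. The balance of calls did: for myoglobin it went from 1268 higher and 1401 lower to 1772 and 1754 with 2 groups only, 710 and 699 without replicate 3, 1598 and 1560 without replicate 4, and 1926 and 1868 without replicate 4 of myoglobin with dexamethasone. For both agents it went from 2029 and 2132 to 1961 and 1948 without replicate 4, and it turned without each 1 of the 4 libraries with both agents (most widely to 2052 and 1940). Called lists for dexamethasone went from 4 up and 3 down to 3 and 4 with quantile normalization, without replicate 1, without replicate 4, and without replicate 4 of myoglobin with dexamethasone. No scaling moved the median change of all genes beyond -0.0443 (library totals, both agents against vehicle). The gene counts for myoglobin, dexamethasone within myoglobin and both agents stayed within 1.5 times the reported 2669, 1016 and 4161 in 11, 9 and 12 of 13 settings that keep all replicates. The exceptions at a threshold of 0.01 were 1588, 397 and 2362 genes, by construction. Library weights gave 4314 and 1625 genes for the first 2, with a weight of 0.148 for replicate 4 of myoglobin with dexamethasone. A fit to 2 groups only gave 639 for dexamethasone. With the replicate number as a block, the counts were 3503, 1788 and 5272, and the NF-kB list was called down for dexamethasone (adjusted p 0.0293, against 0.0885). The pairing check behind the block correlated the deviations of libraries with the same number. It gave 0.0953 to 0.456 for myoglobin against vehicle, -0.0151 to 0.379 for dexamethasone, and 0.0224 to 0.289 for both agents. Not every pair exceeded 0.1, so the block stayed an alternative. The main fit thus leaves out a pairing by number that may exist. Of the 12 libraries, 10 correlated best with one of their own number, a hint from the data only. Leaving out replicates, 1 library or 1 number at a time, gave 1409 to 3794, 315 to 1284 and 2432 to 4225 genes. List counts went from 6, 7 and 14 to 1, 1 and 2 with an estimated correlation, 5, 6 and 13 with fry, 4, 8 and 11 without genes of more than 1 list, and to 6 to 7, 7 to 12 and 12 to 13 without replicates. The overlap in opposite directions went from 260 genes to 493 with the block, 10 at 2-fold in both, a mean of 82.8 with split myoglobin libraries, and 65 to 397 without replicates. The overlap in the same direction went from 94 to 210, 1, 31.7 and 19 to 139. Of the named genes that passed, 0 of 58, 7 of 54 and 0 of 39 lost the call without 1 library, 1, 21 and 1 without all libraries of 1 number, and 0, 4 and 0 in other settings at a threshold of 0.05. Of 35 splits of each 8 libraries, only the real one called as many genes. The counts were 2669 against at most 0 in the others, 1016 against 1, and 4161 against 0. Every other split mixes the 2 treatments, which widens the spread within its groups, so low counts there follow from any real difference. The smallest share the splits can give is 1 in 35, and they cannot tell how many of the called genes changed. Count-based tests and their scalings, voom, and the overlap of their calls were not run, because the values are not counts. Where fewer libraries, genes or a stricter threshold does not account for a change, the cause was not tested. Depth limits genes with few reads: 1051 to 2179 genes per library are listed at 0, where a change may not be detectable.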

Other observations

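The 6 gene lists of the first 2 paragraphs were chosen only after values had been seen, so their 18 tests (adjusted together) describe these data and are no independent evidence. Targets of the aryl hydrocarbon receptor rose with myoglobin: 6 of 7 passed, with camera at an adjusted p of 0.0173 with an estimated correlation. Cyp1a1, which oxidises aromatic compounds, rose by 3.59 ± 0.21 on the log2 scale, from 22.3 ± 7.89 to 271 ± 44.8 (n = 4 libraries per group), Cyp1b1 by 2.24 ± 0.071, and the receptor's repressor gene Ahrr by 1.89 ± 0.31. With dexamethasone added, limma called 0 of the 7, against 1 at an unadjusted p below 0.05 (camera adjusted p 0.709). With myoglobin, 11 of 13 acute phase and secreted defence genes rose (adjusted p = 0.00286 with an estimated correlation), among them Hp, haptoglobin, by 0.70 ± 0.089, and Pigr, the receptor that carries antibodies across epithelia, by 0.62 ± 0.096. Of cholesterol synthesis genes 14 of 18 rose with myoglobin against vehicle (camera adjusted p 8.19e-09, adjusted p = 0.246 with an estimated correlation).

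Of 12 sodium transport genes, 6 fell and 0 rose with myoglobin (adjusted p = 0.0293 with an estimated correlation), and with dexamethasone 3 rose and 0 fell (adjusted p = 0.00828 with an estimated correlation): Scnn1a, Sgk1 and Usp2, a deubiquitinase (1.22 ± 0.097). Of these 3, Usp2 also fell with myoglobin (-0.72 ± 0.097), and the 2 contrasts share the myoglobin libraries. Without replicate 4 of myoglobin with dexamethasone, Atp1b1 and Slc12a2 also passed upwards with myoglobin (adjusted p 0.00424 and 0.00262, against 0.337 and 0.219). Of 17 clock genes 5 rose and 4 fell with dexamethasone, without a call of the list (camera adjusted p 0.638). Per1 and Per2 (0.60 ± 0.047) rose, and Nr1d1 (-1.05 ± 0.15) and Dbp (-0.35 ± 0.099) fell, Dbp without passing when replicate 4 of myoglobin with dexamethasone is left out (adjusted p 0.0546, against 0.0436). Of 20 interferon response genes 1 fell with dexamethasone (camera adjusted p 0.0385, adjusted p = 0.515 with an estimated correlation).

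Nos2, Tnf and Gpr84, which activated macrophages also make, rose with myoglobin. No list of such transcripts was tested. Immune cells in the myoglobin cultures would bring their abundant transcripts. The median log2 change of Ptprc, Csf1r, Tyrobp and Laptm5 was -0.309, and only 1 of the 4, Ptprc, reached a mean of 10 with myoglobin. These values show no gain of immune cells with myoglobin. Csf1r, Tyrobp and Laptm5 lie near the floor in both groups, so their changes say little. Of 6 tested immune markers 1 rose (Cd74, by 1.03) and 1 fell (Ptprc). Immune cells that were present in both groups and were activated by myoglobin stay open as a source. Endotoxin or another contaminant of the myoglobin preparation may be a source as well: 32 members of the NF-kB list rose, which either agent would give, and it cannot be told apart from myoglobin itself, since no library was given a contaminant alone. A response of the epithelial cells to myoglobin stays open as a hypothesis.

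Of 23 distal nephron markers 13 fell with myoglobin, which a lower share of distal cells could give. The list was not called by camera with an estimated correlation (adjusted p 0.0871). Of the 23 markers, 3 rose past the threshold (Slc26a4, Calb1 and Wnk1), which argues against an even loss of all distal cells as the whole cause. A loss together with rises of single genes in the remaining cells is not excluded. The interquartile range of the changes was 1.03 (-1.07 to -0.035). It lies between the bounds set beforehand for and against an even loss, and so decides neither way. The loss of 1 distal cell type, and lower transcription in cells that remained, stay open.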
